A study of Arabidopsis thaliana with 6 samples.

How the data were processed

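RNA from young leaves of Arabidopsis thaliana was measured on 6 NimbleGen long-oligonucleotide arrays in 1 colour (Cy3), 2 arrays for each of 3 genotypes: wild type (Col-0), kyp and cmt3. Plants had grown for 4 weeks on soil in long days, per the labels. Nothing in the labels says whether the 2 arrays of a genotype came from separate plants or extractions, so the p-values measure the spread between these arrays, which may be technical. The labels name no allele of either mutant.

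The values analysed were the deposited intensities, on a linear scale, which the authors had normalized by RMA, per the labels. The RMA settings, the scanner and the software version are not given in the sources used here. Each array held 1 value for each of 30361 gene models, summarised from 1 to 3 probes (19073 models from 2 probes, 11283 from 3 and 5 from 1). The intensities ranged from 10.6 to 64963, and the median of an array lay between 946 and 997. The table of the whole series held the same numbers, with 0 values that differed. A column of standard errors beside the intensities was not used, since its meaning is not stated. The files carry no background, detection or control-probe values, so no gene was called present or absent. A fold change that starts from the lowest 25% of the intensities is a fold of intensity, which can understate the change in transcript. Intensities near the upper end of the range can be compressed in the same way. No total count exists for an array, and the number of arrays limits the precision.

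Loci, descriptions and coordinates were taken from the per-array files, whose gene models are marked Release 6; the coordinates are printed as given there. Symbols were added by locus from the RefSeq annotation of TAIR10.1, which matched 29976 of the 30361 loci, and no coordinate of that assembly was used. A locus counted as a transposable element gene where its description in the files names a transposon, a retroelement or an element family, which gave 2465 genes (916 gypsy, 483 copia, 340 CACTA, 303 LINE, 279 Mutator, 77 hAT and 67 other). Probe sequences were not used here, so whether a probe also binds related copies of an element, or the opposite strand, is open.

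Intensities were transformed to log2, and group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) in 1 fit over all 6 arrays, without a block. The fit had 3 residual degrees of freedom and 1.41 prior degrees of freedom. The 3 comparisons were kyp with wild type, cmt3 with wild type, and kyp with cmt3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 30361 models, with no filter. Errors given with log2 changes are limma's standard errors. Sets were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 20 gene lists, and repeated with an estimated correlation. In the repeat camera also uses the few residual degrees of freedom of the fit. A call lost there is therefore not by itself a sign of correlation between the genes. For lists that passed at the preset, however, the estimated correlation was 0.18 (heat shock), 0.43 (jasmonate), 0.50 (cell division), 0.50 (salicylic acid), 0.71 (glucosinolate) and -0.04 (seed storage). All but that of seed storage lay above the preset 0.01, so the preset p-values of those lists may be too small. A second test, fry, was fixed beforehand as well and asks whether a set moved, without setting it against the other genes. Of the 262 members of the lists, 260 were on the array. The lists were DNA methyltransferases and maintenance, the H3K9 methyltransferase family with IBM1, DNA demethylases, RNA-directed DNA methylation, other silencing factors, loci known to be silenced by DNA methylation, photosynthesis, salicylic acid and defence, jasmonate and wounding, heat shock, cold and drought, the circadian clock, flowering and floral organ markers, root markers, seed storage markers, senescence, cell division, flavonoid synthesis, glucosinolate synthesis and reference genes.

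The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For each mutant against wild type, the rule took KYP and CMT3, the 6 transposable element genes and 6 other genes that rose most, and the 6 genes that fell most, among called genes with both mutant arrays on the same side of both wild type arrays. For kyp against cmt3 it took the 5 called genes with the largest change in each direction. From each list it took up to 4 called members or, where none was called, the member with the smallest p. Other genes that are named, among them further list members that passed adjusted over the list alone, were chosen after their values were seen.

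The image names in the files place both wild type arrays and kyp replicate 1 on slide 1, and kyp replicate 2 and both cmt3 arrays on slide 2. Every comparison was therefore repeated with the slide as a block, which leaves 2 residual degrees of freedom and gives kyp against wild type as the value within slide 1 and kyp against cmt3 as the value within slide 2. Within each slide kyp is 1 array. The value for cmt3 against wild type joins the 2 slides through the difference between the 2 kyp arrays. A p-value with the block therefore does not measure the spread between kyp arrays. Because both mutants are compared with the same wild type arrays, 100 simulations of unchanged groups gave the similarity that sharing them alone produces. Since such groups call almost no gene, as many genes as were called in the data were taken by their p. The simulated noise was independent between genes and held no slide effect. Likeness from a shared slide is therefore left out of the simulated values, and their ranges may be too narrow. The fit was tested on simulated data in which 200 of the 30361 genes were changed per run over 5 runs. It called 20.7% of 2-fold, 56.1% of 4-fold and 78.6% of 16-fold changes for kyp against wild type (20.4%, 57.0% and 78.0% for cmt3 against wild type), with 4.4 and 6.0 false calls per run. Alternatives covered the series table, 3 further normalizations, a filter on dim genes, an intensity trend, robust moderation, array weights, fits of 2 genotypes, the replicate number as a block, another threshold, a minimum of 2-fold, an estimated correlation and leaving out each array. The slide block, a test without genes near CMT3 and KYP, a crossed replicate block and a split of the wild type arrays between the mutants were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.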

Results

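Expression was measured in young leaves of wild type Arabidopsis and of plants mutant in KYP or CMT3, with 2 arrays for each of the 3 genotypes. KYP (SUVH4) is a histone methyltransferase that places H3K9 methylation, and CMT3 is the chromomethylase that maintains CHG DNA methylation. Both act in the silencing of transposable elements, and the design asks which genes change in leaves when either is mutated. Each array gave an RMA-normalized intensity for 30361 gene models, with array medians between 9.89 and 9.96 on the log2 scale. The 2 arrays of a genotype correlated at Pearson's r of 0.986 (wild type), 0.987 (kyp) and 0.987 (cmt3) across genes, and arrays of different genotypes at 0.968 to 0.989. On the first principal component, which held 43.9% of the variance, wild type lay at -61.7 and -56.0, kyp at -16.0 and 7.8, and cmt3 at 47.1 and 78.9. This order follows the slide as well as the genotype, since every array of slide 1 was negative and every array of slide 2 positive. The highest correlation of all pairs (0.989) joined kyp replicate 2 and cmt3 replicate 1, which differ in genotype and share slide 2.

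CMT3 transcript was 3.13-fold lower in cmt3 than in wild type. The mean log2 intensity was 12.60 ± 0.01 (SD, n = 2) in wild type, 12.74 ± 0.06 in kyp and 10.95 ± 0.03 in cmt3, a change of -1.65 ± 0.09 (SE; adjusted p = 0.0159, limma). KYP transcript stood at 10.22 ± 0.04 (SD, n = 2) in wild type, 9.98 ± 0.09 in kyp and 10.34 ± 0.02 in cmt3, and its difference of -0.24 ± 0.10 between kyp and wild type did not pass the test (adjusted p = 0.515). The alleles are not named, so where the 3 probes of KYP lie relative to the mutation is not known and the level checks nothing about the kyp label. CMT3 spans 26251990 to 26257248 on chromosome 1 and KYP 4501449 to 4506190 on chromosome 5.

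In kyp a small number of genes were called higher. The largest rise was that of CYP76C8P (AT3G60955), a cytochrome P450 pseudogene, at 399-fold (log2 change 8.64 ± 0.19 SE), from 4.57 ± 0.14 (SD, n = 2) in wild type to 13.21 ± 0.29 in kyp. Genes of unknown function followed: AT5G26270 rose 211-fold, AT3G54730 rose 132-fold, AT2G16676 rose 125-fold, AT2G40955 rose 70.8-fold and AT2G13450 rose 31-fold. Retrotransposon genes rose with them, led by the copia element AT5G19097 at 88.1-fold (6.46 ± 0.34 SE), the LINE element AT3G44035 at 67.7-fold (6.08 ± 0.23) and the gypsy element AT2G05040 at 59.8-fold (5.90 ± 0.20). In all, 30 genes were higher and 2 were lower in kyp at an adjusted p under 0.05 (limma), and the median rise was 17.0-fold. The files describe CYP76C8P as overlapping a gene on the other strand, and the strand that its 2 probes read is not known. The neighbouring AT3G60950 was also called, at 4.60 ± 0.28 (adjusted p = 0.0389), and is named here after its value was seen.

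Transposable element genes made up 15 of the 30 genes called higher in kyp (50%) against 8.1% of the genes on the array (Fisher's exact test, 2-sided, p = 2.02e-09), and none was called lower. Fisher's test takes genes as independent, which related copies of an element may not be, and its p does not measure the spread between arrays. The copia superfamily gave 5 of the 15, CACTA 4, gypsy 3 and LINE 3, while no Mutator or hAT gene was called. Among copia genes, AT2G17115 rose 37.8-fold, AT3G60170 rose 35.9-fold and AT2G16000 rose 21.5-fold. The 2465 transposable element genes as a set had a median log2 change of 0.08. They passed fry (p = 0.0164) and, narrowly, camera (p = 0.0483), a call that was lost with an estimated correlation (camera p = 0.0738). Within slide 1 the median was 0.08 as well, but kyp is a single array there. The correlation was preset for the tests without 1 array, of which those without kyp replicate 1 (p = 0.252), wild type replicate 2 (p = 0.114) and either cmt3 array (p = 0.0515) ended the call. CACTA was the 1 superfamily of 7 that passed after adjustment (median 0.13, adjusted p = 0.0421), which was also lost with an estimated correlation (adjusted p = 0.101). The estimated correlations of the whole set (0.0051) and of CACTA (0.0014) lay below the preset 0.01. These 2 losses therefore did not come from a higher correlation. In wild type, 68.2% of transposable element genes lay in the lowest 25% of intensities, as did 18 of the 30 genes that rose, so the folds are folds of intensity.

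The 2 genes that fell in kyp were the pseudogene AT2G13480, by 5.40-fold (-2.43 ± 0.15 SE, adjusted p = 0.0383, limma), and AT3G29763 of unknown function, by 3.14-fold (-1.65 ± 0.09, adjusted p = 0.0294). Both calls ended when the variance was allowed to follow intensity (adjusted p = 0.0703 and 0.163).

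Among loci known to be silenced by DNA methylation, QQS, an orphan gene that acts on starch content, rose 6.24-fold in kyp (2.64 ± 0.13 SE, adjusted p = 0.0211, limma). It was the only called member of the 20 lists in this comparison. Adjusted over the list alone, 2 of its 15 measured members were higher and 1 was lower, among them AtMu1, a Mutator element, at 3.60, and ATCOPIA4, a copia element, at -3.14. IBM1, a histone demethylase gene that protects genes from CHG methylation, stood at -0.61 ± 0.12 and did not pass (adjusted p = 0.333). The 15 members had a median of -0.10 and a mean of 0.13 and did not pass as a list (camera adjusted p = 0.988). VIM3 (0.32), DML2 (0.24), AGO4 (0.26) and ATXR6 (0.30), which had the smallest p of their lists of silencing factors, did not pass either.

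Heat shock genes were lower in kyp as a list, with a median of -1.06 and 9 of 10 members below wild type (camera adjusted p = 0.00022; adjusted p = 0.893 with an estimated correlation, which ends the call). No member was called over all genes, and 4 were lower adjusted over the list alone, among them the small heat shock proteins HSP17.6II (-2.30) and HSP23.6 (-2.43) and the chaperone HSP90.1 (-1.96). The cell division list had a median of 0.18, with 14 of 16 members positive (camera adjusted p = 0.0152), led by the cyclin CYCB1;1 at 0.48. This call too was lost with an estimated correlation (adjusted p = 0.893). Within slide 1, the median was -0.79 for heat shock (adjusted p = 0.00072; adjusted p = 0.965 with an estimated correlation) and 0.10 for cell division (adjusted p = 0.175). The cell division list also missed the threshold without wild type replicate 1 (camera adjusted p = 0.0813) and without wild type replicate 2 (0.0631). In the jasmonate list VSP1, a vegetative storage protein, stood at -2.55 and was lower adjusted over the list alone, but not over all genes (adjusted p = 0.0815). The remaining 18 lists did not pass, with medians from -0.51 for cold and drought to 0.23 for salicylic acid and defence (adjusted p = 0.353; median -0.05 within slide 1). The cold and drought list (camera adjusted p = 0.0913) had a median of -0.54 within slide 1, which holds 1 kyp array. Its member COR15A stood at -0.89. Root markers had a median of 0.11, seed storage markers -0.06, flowering and floral organ markers -0.07 and the reference genes -0.03. Within slide 1 the medians of root markers (-0.11), seed storage markers (0.27) and reference genes (0.02) had the other sign. The flowering gene FUL, at -1.40, was lower adjusted over the list alone. For seed storage and flavonoid genes (median -0.08) the median and the direction of the test differed in sign.

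The calls in kyp rest on all 6 arrays: none was kept without any 1 of them, in fits that have fewer residual degrees of freedom. With all arrays, 3104 of the 30361 genes had an unadjusted p under 0.05 (limma), a threshold unlike that of the calls. With the slide as a block 0 genes passed. The median rise of the called genes was then 4.2 on the log2 scale against 4.09, a likeness that their selection favours, since a gene is called where the kyp arrays differ little.

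**Figure D1:**
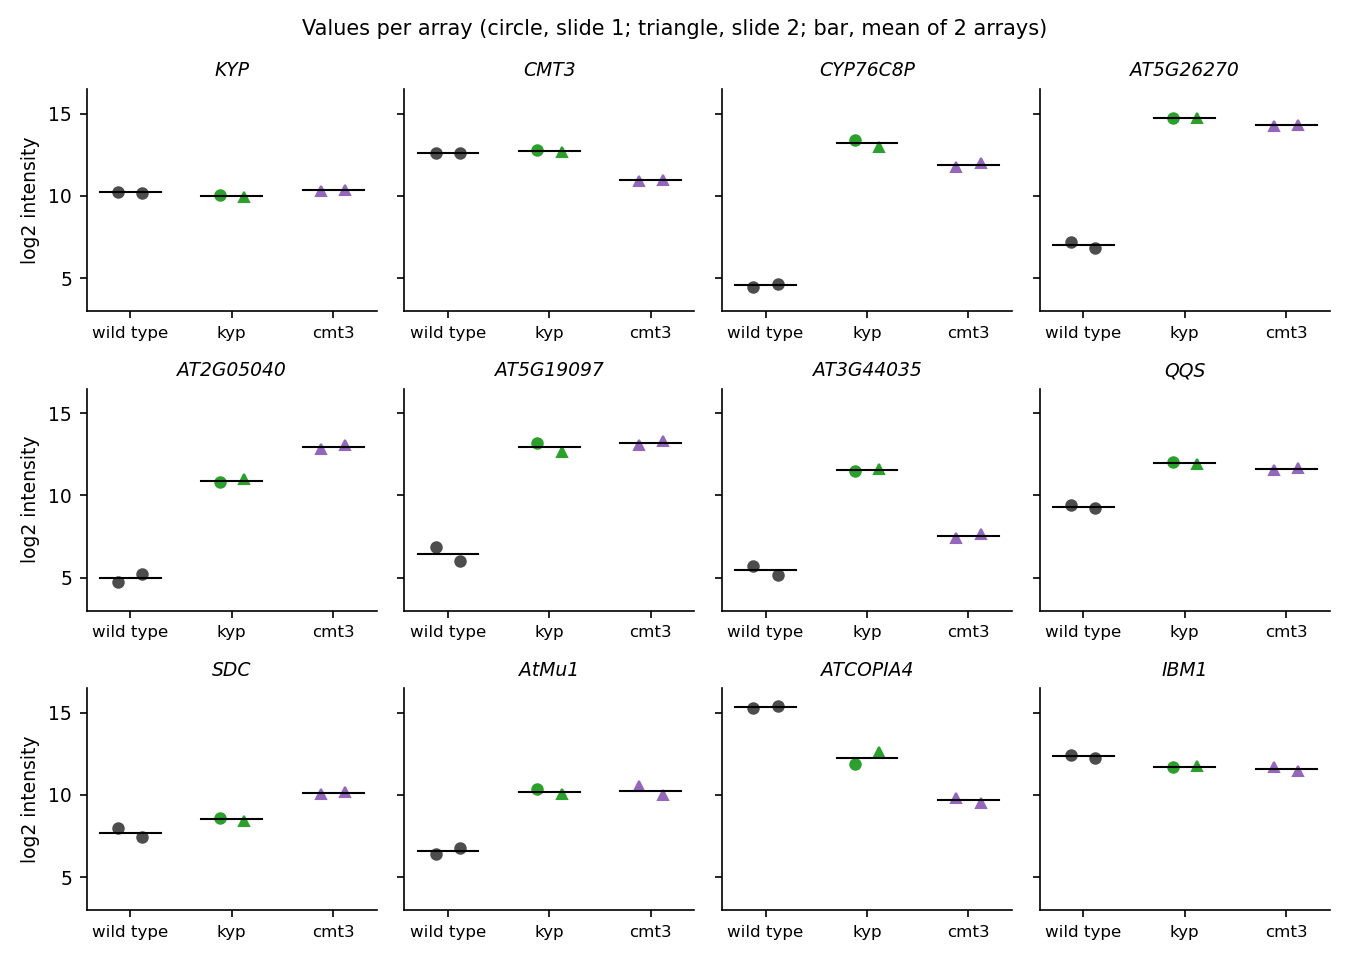
Log2 intensity of 12 genes on each of the 6 arrays (circles, slide 1; triangles, slide 2), with the mean of the 2 arrays of a genotype as a bar. CYP76C8P, AT5G26270, AT2G05040 and AT5G19097 lie above wild type on every mutant array, while ATCOPIA4 stands at 15.36 in wild type, 12.22 in kyp (not called) and 9.68 in cmt3 (called lower).

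In cmt3 the same kinds of gene were called higher, in larger number. The gypsy element AT2G05040 rose 247-fold (7.95 ± 0.20 SE, adjusted p = 0.00256, limma), from 4.99 ± 0.32 (SD, n = 2) in wild type to 12.95 ± 0.19. The copia elements AT3G44215 and AT3G46183 rose 174-fold and 154-fold and the LINE element AT3G29078 rose 162-fold. Outside transposable elements, CYP76C8P rose 162-fold, AT3G54730 rose 161-fold, the pseudogene AT3G32966 rose 158-fold, AT5G26270 rose 155-fold, AT5G28235, annotated as a cysteine-type peptidase, rose 150-fold and AT2G16676 rose 120-fold. Altogether 170 genes were higher and 55 lower at an adjusted p under 0.05, with median changes of 8.96-fold and 3.57-fold. The balance of rises and falls depended on the setting: with an intensity trend 1211 genes were higher and 1061 lower, without the lowest 25% of genes 309 and 183, and at an adjusted p under 0.10 702 and 564. Without cmt3 replicate 1, which leaves a single cmt3 array, the balance turned and falls outnumbered rises.

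Transposable element genes were 83 of the 170 genes that rose in cmt3 and 4 of the 55 that fell. Their share of the rises was 48.8%, against 8.1% on the array (Fisher's exact test, 2-sided, p = 6.48e-45, with the same limit as in kyp). This share was 12.5% with an intensity trend, 31.1% without the lowest 25% of genes and 23.8% at an adjusted p under 0.10. Of those that rose, 26 were copia, 20 LINE, 20 CACTA, 9 gypsy, 5 Mutator and 3 hAT. The mutants lay nearer each other when calls were set aside. At least 4-fold above wild type, with both mutant arrays above both wild type arrays, were 79 transposable element genes in kyp and 140 in cmt3. By the same rule 9 and 11 were lower. The copia elements AT5G19097 and AT1G34090 rose 105-fold each (6.72 ± 0.34 and 6.72 ± 0.44). The set as a whole had a median of 0.07 and did not pass camera (p = 0.242, or 0.208 with an estimated correlation), but it was higher by fry (p = 0.00395). With the slide as a block it passed camera at the preset correlation (p = 0.0199) and at an estimated correlation (p = 0.0361). Before the rise, 103 of the 170 genes lay in the lowest 25% of wild type intensities.

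The copia element ATCOPIA4 (AT4G16870), at 9483974 to 9488416 on chromosome 4, went the other way. Its level was 15.36 ± 0.07 (SD, n = 2) in wild type, and it fell 51.2-fold in cmt3 (-5.68 ± 0.28 SE, adjusted p = 0.0121, limma). In kyp it stood at -3.14 and did not pass (adjusted p = 0.0815). AT1G73490, which encodes an RNA-binding protein, fell most, by 77.6-fold (-6.28 ± 0.24, adjusted p = 0.00725). LRX2, a leucine-rich repeat extensin of the cell wall, fell 24.7-fold, AT5G48570, a peptidyl-prolyl isomerase, fell 15.5-fold, AT3G21320 fell 15.4-fold and HSFA7A, a heat shock transcription factor, fell 10.6-fold. The calls of LRX2, AT3G21320 and HSFA7A ended under robust moderation (adjusted p = 0.0523, 0.0523 and 0.0571).

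Of the loci known to be silenced by DNA methylation, QQS rose 4.90-fold (2.29 ± 0.13 SE, adjusted p = 0.0159, limma), AtMu1 rose 12.7-fold (3.67 ± 0.26, adjusted p = 0.0246) and SDC, an F-box gene silenced by non-CG methylation, rose 5.28-fold (2.40 ± 0.23, adjusted p = 0.0432). SDC lost its call under robust moderation (adjusted p = 0.0544). With ATCOPIA4, 4 of the 15 measured members were called over all genes, and 7 adjusted over the list alone (4 higher, 3 lower). The list as a whole did not pass (median -0.00, mean 0.29, camera adjusted p = 0.754), nor did it with the slide as a block, where its median was 0.52 (adjusted p = 0.0982). IBM1 stood at -0.77 ± 0.12 (adjusted p = 0.0882) and was lower adjusted over the list alone. Apart from CMT3 itself, no member was called in the lists of DNA methyltransferases, H3K9 methyltransferases, DNA demethylases, RNA-directed DNA methylation and other silencing factors, whose medians were -0.03, 0.13, -0.06, 0.10 and 0.04 and which did not pass as lists. DME (-0.32), SHH1 (0.40) and ATXR6 (0.79) had the smallest p of theirs. ATXR6 was higher and ATXR5 (-0.71) lower adjusted over the list alone.

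The heat shock list was lower in cmt3, with a median of -2.38 and 10 of 10 members below wild type (camera adjusted p = 7.2e-05). This call was lost with an estimated correlation (adjusted p = 0.895). The small heat shock protein HSP17.6C stood at -3.91, HSP90.1 at -3.60, HSP17.6II at -3.35, the transcription factor HSFA2 at -3.34 and the disaggregase HSP101 at -2.23. None was called over all genes, and 6 were lower adjusted over the list alone. The jasmonate list was lower with a median of -0.65 and 14 of 15 members negative (camera adjusted p = 0.00066), and lost its call with an estimated correlation (adjusted p = 0.895). Of its members, VSP1 fell 5.21-fold and was called (adjusted p = 0.0456, limma; 0.0571 under robust moderation), and the repressor gene JAZ10 stood at -4.61. The glucosinolate list was also lower (median -0.68, 12 of 15 negative, camera adjusted p = 0.00856), although its regulator MYB28 stood at 0.95. With an estimated correlation it did not pass (adjusted p = 0.895). With the slide as a block, the medians of these 3 lists were -1.72, -0.62 and -0.57, and the glucosinolate list no longer passed (adjusted p = 0.0982), nor did any of them with the block and an estimated correlation (adjusted p = 0.844). It also missed the threshold without wild type replicate 2 (adjusted p = 0.0558) and without the genes near CMT3 and KYP (adjusted p = 0.095).

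In the circadian clock list FKF1, a blue-light receptor of the photoperiod pathway, rose 4.21-fold (2.07 ± 0.18 SE, adjusted p = 0.0379, limma). GI (0.42) and LUX (0.64) were higher adjusted over the list alone, and the list did not pass as a whole (median 0.06, adjusted p = 0.454). FKF1 lies at 25512339 to 25514552 on chromosome 1, within 3 Mb of CMT3. The salicylic acid list had a median of -0.05 (camera adjusted p = 0.454) over all arrays. With the slide as a block the median was -0.96 (camera adjusted p = 0.00318, or 0.844 with an estimated correlation). This move comes only from the difference between the 2 kyp arrays, whose spread the camera p does not measure. No member was called among photosynthesis (median 0.00), cold and drought (-0.14), flowering (-0.04), root (0.06), seed storage (-0.92), senescence (0.20), cell division (0.15), flavonoid (-0.01) or reference genes (-0.01), and these lists did not pass as wholes. With the slide as a block the medians were -0.46 for flowering, -0.18 for root, -0.42 for seed storage and -0.37 for flavonoid genes, and none passed. CBF2 (1.26), SEP2 (AT3G02310, 2.62), ORE1 (1.73) and WRKY70 (1.03) had the smallest p of theirs. Of these CBF2, ORE1 and WRKY70 were higher adjusted over the list alone, and KIN1 (-2.78) was lower.

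**Figure D2:**
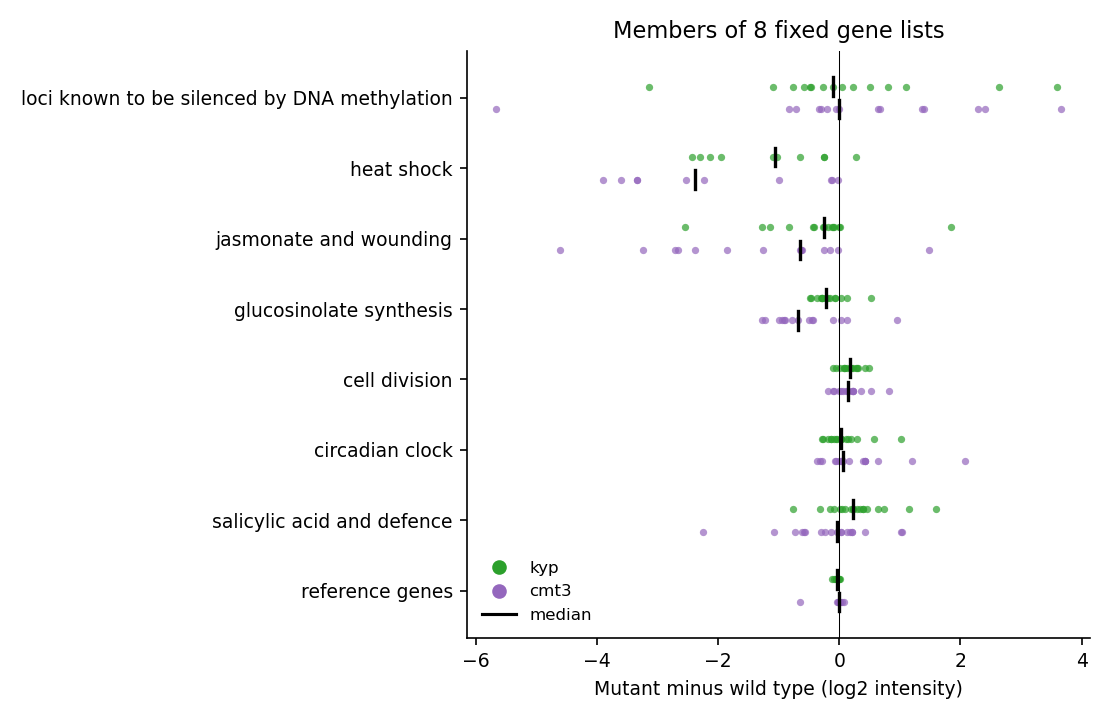
Log2 difference from wild type of each measured member of 8 of the 20 gene lists in kyp (green) and cmt3 (purple), with the median of each list as a black bar. Heat shock members reach a median of -1.06 in kyp and -2.38 in cmt3. The reference genes have medians of -0.03 in kyp and -0.01 in cmt3, although their member UBQ10 stands at -0.65 in cmt3 (not called).

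Leaving out 1 array reduced the 225 calls in cmt3 to between 32 (without wild type replicate 1) and 84 (without wild type replicate 2), with 33 without cmt3 replicate 2, 70 without cmt3 replicate 1 and 39 without either kyp array. All cmt3 arrays were on slide 2 and all wild type arrays on slide 1; with the slide as a block 0 genes passed (limma; 6988 at an unadjusted p under 0.05 without the block). The median rise was 3.32 on the log2 scale with the block against 3.16, which selection favours in the same way. A fit of wild type and cmt3 alone, in which the kyp arrays took no part, called 33 genes higher, and their median rise was 5.52, or 5.81 with the slide as a block.

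Set directly against each other, the mutants differed at 9 genes. AT1G73490 was 82.2-fold higher in kyp than in cmt3 (6.36 ± 0.24 SE), RLP13 (AT1G74170), a receptor-like protein, was 9.99-fold higher (3.32 ± 0.12) and the pseudogene AT5G34800 was 7.07-fold higher (2.82 ± 0.11; adjusted p = 0.03 for each, limma). Between kyp and wild type these 3 differed by 0.08, -0.003 and 0.18, which did not pass (adjusted p = 0.939, 0.996 and 0.642). Lower in kyp were the LINE elements AT1G45030, by 33.3-fold (-5.06 ± 0.21), and AT2G15510, by 17.7-fold (-4.15 ± 0.15), the pseudogenes AT1G45035, by 23.9-fold (-4.58 ± 0.12), and AT3G32966, by 13.1-fold (-3.71 ± 0.12), and AT4G18150 of unknown function, by 6.57-fold (-2.72 ± 0.13). The call of AT4G18150 (adjusted p = 0.0421) ended under quantile normalization (0.0552), under cyclic loess (0.0544) and without the genes near CMT3 and KYP (0.0504). A sixth gene, the LINE element AT3G43575 (-2.13), was called as well; it falls outside the rule for named genes. AT1G45030 and AT1G45035 are neighbours on chromosome 1, at 17031664 to 17032035 and 17032053 to 17032822.

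AT1G73490 and RLP13 start at 27636927 and 27895155 on chromosome 1, 1.38 and 1.64 Mb from CMT3. Within 3 Mb of CMT3, 15 genes besides CMT3 were called in cmt3 against wild type, among them AT1G70430, a protein kinase gene (2.05), the fucosyltransferase gene FUT13 (1.51) and DR4 (4.87), with kyp at 0.35, 0.07 and 0.88. These 3 were named after their values were seen.

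**Figure D3:**
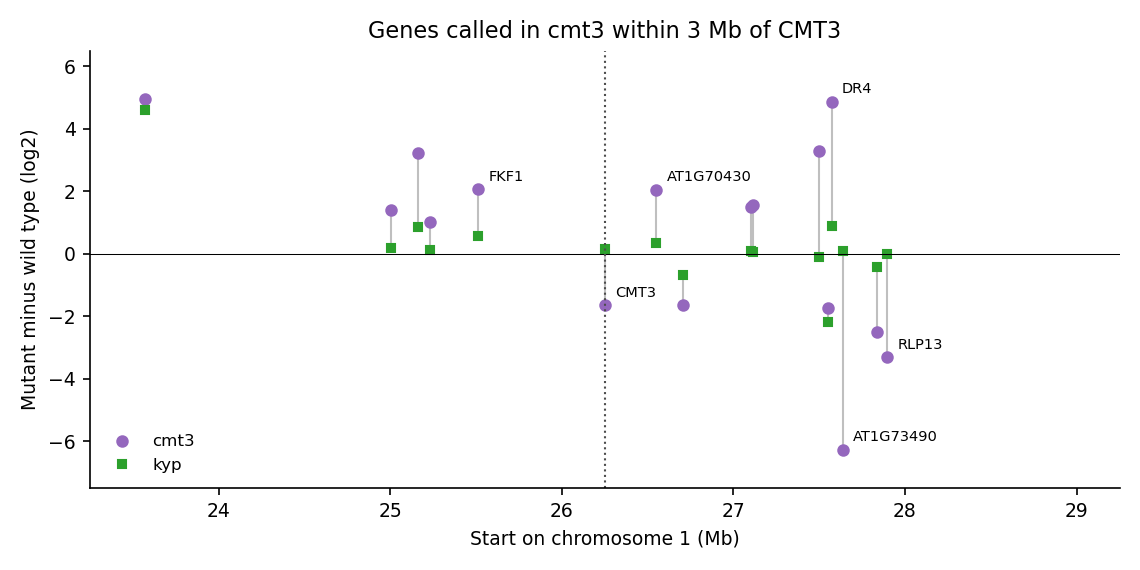
Log2 difference from wild type in cmt3 (circles) and kyp (squares) of the genes called in cmt3 that start within 3 Mb of CMT3 (dotted line), by position on chromosome 1; a grey line joins the values of 1 gene. AT1G73490 stands at -6.28 in cmt3 and 0.08 in kyp, and DR4 at 4.87 and 0.88.

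The LINE element AT3G44035 was the only gene called higher in kyp and not in cmt3 against wild type. In cmt3 it stood 4.29-fold above wild type (adjusted p = 0.0561), and the difference between the mutants, 3.98 in favour of kyp, did not pass (adjusted p = 0.0767). Transposable element genes as a set did not differ by camera (median -0.02, p = 0.836, or 0.796 with an estimated correlation) or by fry (p = 0.0955). By camera, 5 lists were higher in kyp than in cmt3: jasmonate (median 0.64, adjusted p = 0.0123), heat shock (0.73, 0.0139), salicylic acid and defence (0.25, 0.0139), seed storage (0.62, 0.0169) and glucosinolate synthesis (0.49, 0.0259). None of them kept its call with an estimated correlation (adjusted p from 0.921 to 0.925), and none passed without kyp replicate 2. Within slide 2 the medians were 0.55, 0.51, 0.87, 0.61 and 0.44, and heat shock (adjusted p = 0.0502) and glucosinolate synthesis (adjusted p = 0.115) no longer passed, nor did any of the 5 there with an estimated correlation (adjusted p from 0.825 to 0.87). Without cmt3 replicate 2 the salicylic acid (adjusted p = 0.0873), seed storage (0.0556) and glucosinolate (0.222) lists missed the threshold. Without the genes near CMT3 and KYP the salicylic acid (0.0693), heat shock (0.0891) and glucosinolate (0.0693) lists did. No list member was called over all genes. Adjusted over the list alone, HSP101, HSP17.6C and HSP90.1 were higher in kyp, as were CMT3 and ATCOPIA4, while SDC, FKF1, SEN1 and ORE1 were lower. Without any 1 array, limma called 0 genes between the mutants, and with the slide as a block also 0 (3796 at an unadjusted p under 0.05 without it).

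Of the 30 genes higher in kyp, 29 were also called higher in cmt3, and both genes that fell in kyp fell in cmt3. Independent lists would share 0.168 higher and 0.00362 lower genes, a value that leaves out the shared wild type arrays. Unchanged groups simulated against those arrays, with the same numbers of genes taken by the smallest p, shared a mean of 14.9 higher (range 9 to 21) and 1.06 lower genes (range 0 to 2). These simulations hold no slide effect, while kyp replicate 2 and both cmt3 arrays were on slide 2 and wild type was on slide 1. No gene was called in opposite directions. None was in any simulation either, but there the count was taken at an adjusted p under 0.05, where unchanged groups call almost no gene. It therefore does not tell the data from unchanged groups. Conversely, 167 of the 170 genes higher in cmt3 were positive in kyp, where their median was 1.81 against 3.16 in cmt3. In the simulated groups, a mean of 146 of 170 genes taken in this way were positive in the other group (range 136 to 157). Of the 83 transposable element genes higher in cmt3, 70 stood at least 2-fold above wild type in kyp, against a mean of 13.4 of as many in the simulations (range 7 to 21). Of the 55 genes lower in cmt3, 52 were negative in kyp (median -1.16 against -1.84), which lay within the range of the simulations (39 to 54, mean 48.0). Of the 30 genes higher in kyp, 2 were called different between the mutants, both rising further in cmt3. They were AT3G32966, with changes of 3.60 in kyp and 7.30 in cmt3 (adjusted p = 0.03 for the difference), and AT4G18150, with 3.59 and 6.31 (adjusted p = 0.0421). For the other 27 genes that rose in both, the difference between the mutants did not pass (adjusted p from 0.079 to 0.955, limma). It ran from -2.58 for AT5G07215 (adjusted p = 0.079) and -2.05 for AT2G05040 (adjusted p = 0.193) to 1.3 for CYP76C8P (adjusted p = 0.285) and 1.44 for AT3G60950 (adjusted p = 0.359), with kyp below cmt3 in 18 of the 27. AT5G07215 and AT3G60950 were named after their values were seen.

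Across all genes, which are not independent replicates, the log2 changes in the 2 mutants correlated at r = 0.674 and Spearman's rho = 0.596. Unchanged groups simulated against the same wild type arrays gave 0.5 (range 0.475 to 0.522) and 0.441, and a covariance of 0.083 against 0.239 observed, a difference of 0.157. A split with 1 wild type array for each mutant, so that none was shared, was made after the data had been seen. It gave r = 0.331 and a covariance of 0.150 with wild type replicate 1 set against kyp and replicate 2 against cmt3, and r = 0.357 and 0.156 the other way round. Both wild type arrays were on slide 1, so the split does not part the slide from the genotype. The calls themselves were not split, so part of their overlap may come from the shared arrays or the shared slide.

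**Figure D4:**
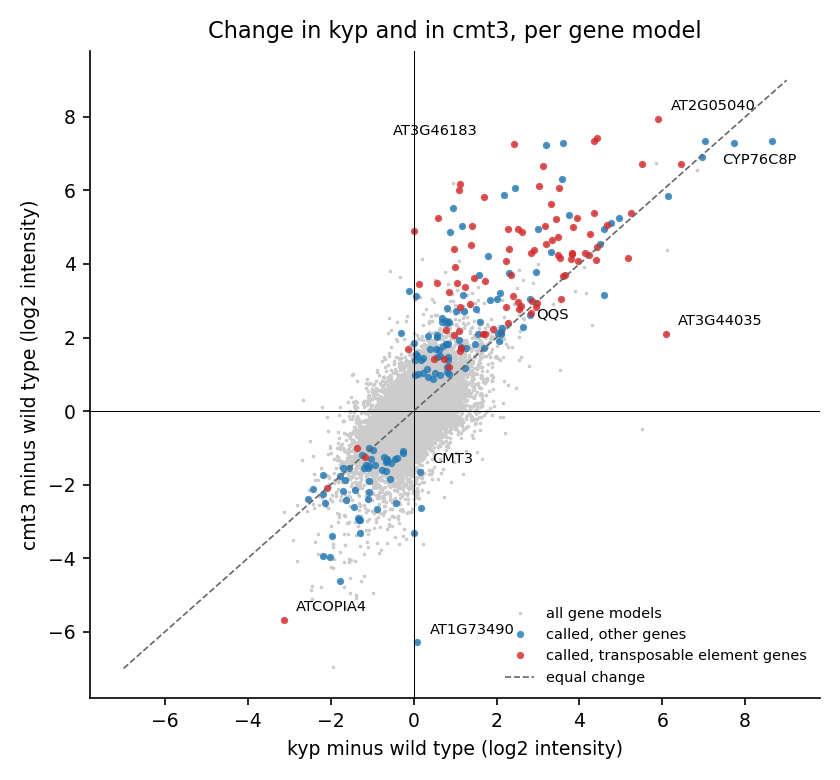
Log2 difference from wild type in kyp (horizontal) and in cmt3 (vertical) of each of 30361 gene models (grey), with genes called in either comparison in red (transposable element genes) and blue (others); the dashed line marks equal change. Most called genes lie in the quadrants of equal sign, with r = 0.674 across genes, and AT1G73490 lies at -6.28 in cmt3 and 0.08 in kyp.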

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

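The slide block, the test without genes near CMT3 and KYP and the crossed replicate block were chosen only after the data had been seen. Values near the lower or upper end of the intensities limit the size of a change that can be read, and no background level was measured. No named gene changed sign in the 19 alternatives in which single genes were recomputed; the estimated correlation, the 2-fold minimum and the crossed replicate block gave no values for them. Of the 47 named results that were called, 37 lost the call in fits of 2 genotypes, 36 with the replicate block, 47 with the slide block, and 34 to 40 without 1 array.

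The number of called genes (kyp with wild type 32, cmt3 with wild type 225, kyp with cmt3 9; 31 shared by both mutants) stayed within 1.5 times under the series table, the 3 normalizations, robust moderation, array weights and a minimum of 2-fold. Without the lowest 25% of genes they were 63, 492 and 17, with 62 shared and 34 transposable element genes for kyp with wild type and 5 for kyp with cmt3; fewer genes were tested. With an intensity trend they were 85, 2272 and 24, with 83 shared, and 39, 162 and 10 of them transposable element genes; the cause was not tested. At an adjusted p under 0.10 they were 102, 1266 and 19, with 101 shared, and 51, 182 and 5 transposable element genes.

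Fits of only the 2 genotypes compared, with fewer arrays, gave 0, 39 and 0 calls, 0 shared, 0, 17 and 0 transposable element genes, 4 lists for kyp, and CMT3 at -1.65 (adjusted p = 0.0719, limma). The replicate number as a block gave 0, 69 and 0 calls, 0 shared, 0, 29 and 0 transposable element genes, and CMT3 at -1.65 (adjusted p = 0.0637); it changed no list or set test. The deviations of same-numbered arrays correlated at -0.12 (wild type and kyp), 0.004 and -0.04, which gives no sign of a pairing by number. The 2 kyp arrays also differ in slide, so these values do not settle which arrays belong together. A block with the kyp numbers crossed gave 4, 23 and 0 calls. The slide block, with fewer degrees of freedom, gave 0, 0 and 0 calls, 0 shared and 0, 0 and 0 transposable element genes, CMT3 at -1.56 (adjusted p = 0.319), and 3 lists for kyp with cmt3. Without genes near CMT3 and KYP, 2 lists passed for kyp with cmt3. At an estimated correlation 0, 0 and 0 lists passed. By fry no list passed in any comparison, with smallest adjusted p of 0.349, 0.0683 and 0.237.

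The transposable element set for kyp missed the threshold under quantile normalization (camera p = 0.0502), median centring (0.0662), an intensity trend (0.0879), only 2 genotypes (0.0515) and an estimated correlation (0.0738). For cmt3 it passed under cyclic loess (0.0453), without the lowest 25% of genes (0.00922) and with the slide block (0.0199). The cause was not tested.

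Leaving out each array in turn gave 0 to 0, 32 to 84 and 0 to 0 calls, 0 to 0 shared, and 0 to 0, 9 to 33 and 0 to 0 transposable element genes. Lists that passed numbered 1 to 4, 2 to 5 and 0 to 5. At the preset correlation the set test p ranged over 0.00534 to 0.252, 0.117 to 0.326 and 0.372 to 0.952, and turned direction for kyp with cmt3 without kyp replicate 2 (camera p = 0.658). KYP in kyp ranged from -0.30 to -0.18 and CMT3 in cmt3 from -1.67 to -1.63. An array left alone in its group was assumed to vary like the others.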

Other observations

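All tests here except that of closeness to transposable element genes were chosen only after the result was seen, and the genes named below were chosen after their values were seen. Among the 55 genes that fell in cmt3, ACS8, which encodes an enzyme of ethylene synthesis, fell 7.85-fold (-2.97 ± 0.24 SE, adjusted p = 0.0301, limma), LOG6, a cytokinin-activating enzyme gene, fell 6.39-fold, GH3.3, an auxin-conjugating enzyme gene, fell 5.30-fold, ATGA2OX3, which inactivates gibberellin, fell 4.61-fold and the auxin-responsive IAA2 fell 2.58-fold. In kyp these 5 genes stood at -1.32, -0.89, -1.64, -1.09 and -0.65, and none was called. The floral repressor MAF5 fell 4.77-fold in cmt3 (-2.25 ± 0.23, adjusted p = 0.0491), while FD, a partner of FT in flowering, rose 2.06-fold and the trichome regulator GIS rose 5.41-fold (2.43 ± 0.20, adjusted p = 0.031).

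Genes that were called in cmt3 with little or no change in kyp lay near CMT3 more often than the other called genes did. Of 15 called genes within 3 Mb of CMT3, 10 had a change in kyp under 0.25 of that in cmt3, against 21 of 209 elsewhere (Fisher's exact test, 2-sided, p = 1.16e-06), and no other window of that size held more than 3. An even spread along the chromosomes would place 1.59 there (exact binomial test, 2-sided, p = 2.12e-06), which argues against loss of CMT3 acting alike everywhere. Of the 10, 7 rose, which weaker probe binding to a variant segment does not give, and 3 fell (AT1G73490, RLP13 and AT1G74010), for which weaker binding and lower transcript cannot be told apart because probe sequences were not used. A candidate explanation is a segment linked to the cmt3 mutation that differs from the wild type; a local effect of the mutation stays open and untested.

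Heat shock genes were lower in both mutants, at medians of -1.06 in kyp and -2.38 in cmt3 (camera calls that were lost with an estimated correlation, adjusted p = 0.893 and 0.895). As the whole cause of the change in cmt3, an offset between the slides would need kyp replicate 2 to lie below kyp replicate 1 by about as much, but the median difference was -0.394 (SD over 10 members 0.51), although within slide 2 only 6 of 10 members were lower in both cmt3 arrays than in kyp replicate 2 (median -0.51). For kyp, the median of kyp replicate 1 minus wild type within slide 1 was -0.791 (SD 0.78). With the slide as a block, camera gave adjusted p = 0.00072, and adjusted p = 0.965 with an estimated correlation. An offset between slides does not give a difference within 1 slide. However, this rests on 1 kyp array, and the 2 wild type arrays differed by a median of 0.569. Variation between arrays therefore cannot be told apart from a change, and the slide as the whole cause in kyp is not decided. Another time of day at harvest could not be decided: 6 evening and 5 morning clock genes moved apart by 0.5 in cmt3 and 0.21 in kyp, too few genes and too small a shift to settle it. Without FKF1, which lies within 3 Mb of CMT3, the shifts were 0.496 in cmt3 and 0.099 in kyp. Loss of KYP or CMT3, and the conditions of the plants, stay open and untested.

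For genes higher in cmt3 an offset between slides was weighed on the 33 called in a fit without kyp, since a fit over all arrays picks genes on which the kyp arrays differ little. Their median difference between kyp replicate 2 and kyp replicate 1 was -0.261 (SD over genes 0.50) against a median rise of 5.52, and 0 of the 33 had at least 50% of the rise between the kyp arrays, which argues against the slide as the whole cause for these genes. Of the 33, 30 were among the 170 genes higher over all arrays, and for the remainder of the 170 the slide stays open. Loss of CMT3 stays open, as untested.

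A hypothesis set before its result was seen was that genes other than transposable elements that rose in cmt3 lie close to such elements. Of 87 such genes, 21 were pseudogenes, against 1196 of 27896 genes other than transposable elements on the array. A transposable element gene lay within 2 kb of 32 of the 87 (36.8%), against 6.0% of 27648 other genes. At a matched local density 16.4 were expected (permutation test, 1-sided, p = 2e-05). The matching used 9 bins of density, so a difference in density inside a bin stays open. The closeness could also come from spread of the change from a neighbouring element, or from element sequence annotated as a gene, which were not tested.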
